A study of Mus musculus with 2 samples.

How the data were processed

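Bisulfite-converted genomic DNA was sequenced from cultured mouse (C57BL/6) adipose progenitors, per the labels' protocols. Bisulfite treatment converts unmethylated cytosine to uracil, so that cytosines still read as cytosine mark methylated positions. The labels give 1 library of CD137+ progenitors and 1 library of PDGFRα+ progenitors. Both were exposed to dexamethasone (DEX), a synthetic glucocorticoid. Cells had been isolated by magnetic sorting from subcutaneous or visceral fat and then differentiated, per the labels' protocols, and the labels do not say which depot each library came from. CD137 is the product of Tnfrsf9, and PDGFRα (CD140a) is the product of Pdgfra.

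The values used come from the authors' deposited list of differentially methylated regions between the 2 libraries. It holds a position and a signed score per region, and no header. The genome build is mm10, per the submitters' processing notes. The aligner, the region caller, its thresholds and the read coverage are not given in the sources used here. The deposited score is therefore used only to describe, rank and filter regions within this list, by its sign and its size. It is not a methylation level or a percent difference, and no read depth, number of CpG sites or level per library stands beside it. The depth behind each region is unknown, so no coverage filter, interval on a level or test of a single region was computed. Tested on the list itself, no regions overlapped (0), none had a score of 0, the narrowest was 51 bp and the smallest gap between neighbours was 50 bp. Positions are printed counting from 1, taking the list as BED.

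The sign of the score is not defined in the list. The list's title puts the PDGFRα+ sample first and the CD137+ sample second. If the score is first minus second, a negative score means lower methylation in the PDGFRα+ library. The text keeps to "negative" and "positive" score because that order of subtraction is not stated. With 1 library per group there is no replicate error, and no p-value was computed. Intervals on a share of regions are 95% Wilson intervals. The only other interval, on a median score per bp, is a 95% interval from order statistics. Both cover the counting of regions only, which are not independent replicates.

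Genes were placed with a RefSeq table of the GRCm38.p6 assembly, the assembly that mm10 names, which gave 49943 genes on the chromosomes, 21887 of them protein-coding. The table has gene starts and ends but neither strand nor exons. Promoters, exons, introns and untranslated regions could therefore not be told apart. A "gene end" here is the stretch from 2000 bp outside to 500 bp inside either end of a gene, and 5 kb was added on both sides of a gene where the plan had named 5 kb upstream. Regions were assigned to gene ends first, then to gene bodies, and the rest were called intergenic. The observed shares were compared with 1000 random placements that kept each region's chromosome and width. A planned search for glucocorticoid receptor and TEAD motifs was not run, because no genome sequence was used here.

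A total of 18 gene lists were fixed before the data were examined. For each list the number of members with a region in the gene or within 5 kb was compared with 10000 random lists of the same size, matched on gene class (protein-coding or other) and on 10 classes of gene length. A list is described as standing above chance when its count reached percentile 97.5 of the random lists, a description of these 2 libraries and not a test of the groups. Symbols were matched directly or, where they named 1 gene only, through the table's synonyms (Nespas is listed as Gnasas1), and each found a gene. Some genes belong to more than 1 list. A region near several genes counts for each of them, but shares of negative regions count each region once. Members of one cluster, such as the HOX genes, share regions, whereas random lists are scattered, which widens the gap between the clustered lists and chance. CpG content was not matched. On simulated regions, 5% of 100 unchanged lists of 25 genes reached percentile 97.5 or stood at 2.5 or below, and 80% and 100% of the lists in which the odds of a region were raised 4-fold and 9-fold reached 97.5 (20 lists each). The unchanged lists were random protein-coding genes and the simulated regions lay at random along each chromosome, so a rate near 5% was built in. It does not show how often chosen lists would reach the threshold with regions that cluster as the real ones do. The overlap counts differed from direct counting for 0 of 1374 genes and 0 of 913 regions of chromosome 19.

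A rule for naming genes was set before the data were examined, using promoters and a region statistic or methylation difference. The gene table lacks strand and the list names no such measure. Gene ends therefore replaced promoters, and the absolute score replaced the planned measures. The genes named in the text follow this changed rule. They are Tead1, Pdgfra, Tnfrsf9 and Nr3c1; per sign, the 8 protein-coding genes with the largest absolute score at a gene end and the 5 with the largest in the gene body; the 5 with most regions; and up to 4 members per list. Some genes that this rule names are not reported here. Further members of the fixed lists, and all gene families in the closing section, were chosen after their values were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives tried were other gene-end windows, a stricter overlap, protein-coding genes only, merging of neighbours, weighting by length, autosomes only, an absolute score of at least 100, a width of at least 100 bp, local random shifts, other backgrounds for the lists, and leaving out the list members with most regions. Those on score, width, shifts, background and left-out members were chosen after seeing the data.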

Results

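Whole-genome bisulfite libraries of dexamethasone-treated CD137+ and PDGFRα+ adipose progenitors (1 library each) were compared, and the authors' list gave 34139 differentially methylated regions between them. The cells had been differentiated after sorting, per the labels' protocols. CD137 is a marker linked to beige adipocyte precursors, and PDGFRα marks adipose progenitors more widely. The series title frames the comparison as a question about glucocorticoid action, the methylation of the TEAD1 gene and visceral obesity. No untreated library was compared, so no region can be read as an effect of dexamethasone. Each region carried only the authors' signed score. The list does not define the sign. If it is PDGFRα+ minus CD137+, the order in which the list names the samples, a negative score means lower methylation in the PDGFRα+ library. The depth of each library is unknown, and with no replicates no difference could be set against a replicate spread.

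Regions with a negative score outnumbered those with a positive score by about 2 to 1. There were 22993 negative regions, or 67.4% of all (95% interval 66.9 to 67.8), and 11146 positive regions. The largest positive scores stood at Ebf3, Mab21l1 within Nbea, Osr1 and Prrx1, and the largest negative scores at Tbx1, in the HoxA cluster around Hoxa5 and Hoxa6, and at Tmem267. Regions were short, with a median width of 112 bp (quartiles 80 and 182), and together covered 5320.2 kb. The median absolute score was 49.3 among positive and 49.5 among negative regions. It was 67.5 among regions at least 100 bp wide, against 49.4 over all. Scores thus rose with width, and a strong region need not have a larger methylation difference. Wider regions were more often negative, with 65.0% negative (64.2 to 65.8) among the 14444 regions under 100 bp and 73.8% (72.0 to 75.4) among the 2555 regions of 300 to 500 bp. By score, classes below an absolute score of 500 were 66.5% to 67.7% negative. The share was 60.3% (49.2 to 70.4) of 78 regions from 500 to 1000, and 50% (26.8 to 73.2) of the 14 strongest.

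The regions were spread over all autosomes at 11.1 (chromosome 7) to 16.2 (chromosome 8) regions per Mb, 13.7 when pooled. Chromosome X held 557 regions, or 3.26 per Mb, which was 4.21 times lower than the pooled autosomes and below every single autosome. Chromosome Y held 15 regions. The negative share varied little, from 65.3% on chromosome 13 to 69.6% on chromosome 12, and was 68.4% (64.4 to 72.1) on X.

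**Figure D1:**
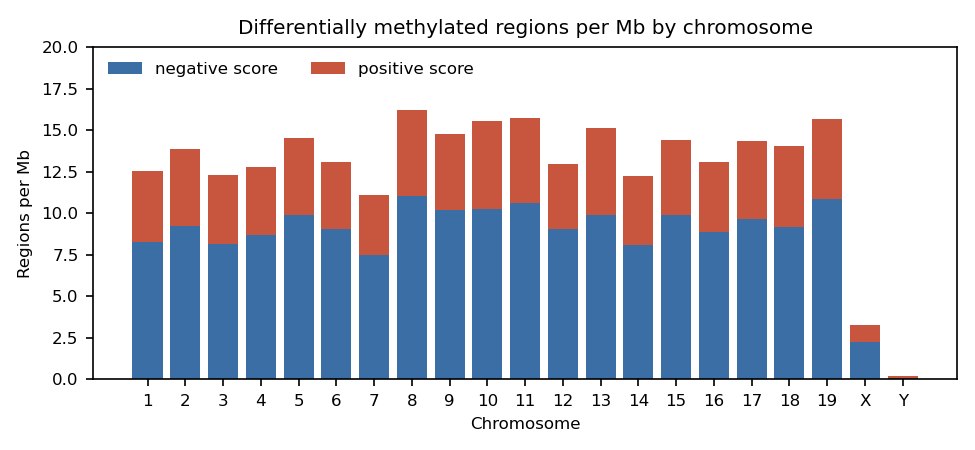
Regions per Mb (vertical axis) on each chromosome (horizontal axis), with the bar split into negative (blue) and positive (red) scores. The autosomes lie between 11.1 and 16.2 regions per Mb and X at 3.26.

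Within chromosomes, regions lay at genes more often than random placements did. The placements kept chromosome and width only, so CpG content and read coverage were not matched. Gene ends held 3679 regions, or 10.8% (10.5 to 11.1), against a mean of 8.85% over the random placements, whose highest value was 9.37%. A further 54.4% lay in gene bodies against 44.4% at random, and 34.9% were intergenic against 46.7%. When regions were instead moved at random by up to 500 kb, which keeps the local density, the fold over random placement was 1.06 for gene bodies and 1.10 for gene ends, against 1.22 for both over whole chromosomes. Gene ends held 11.04% of positive and 10.65% of negative regions, a difference inside the central 95% of 1000 shuffles of the signs. It was larger for regions of absolute score 100 or more, at 17.5% of positive and 14.7% of negative regions, and in the narrower gene-end window, at 5.79% and 5.25%. Both of these lay outside the central 95% of the shuffles (percentiles 0.6 and 2.45), also when the signs were moved along the list as a whole to keep runs of 1 sign (0.8 and 1.55). The 3 other settings tried lay inside. Of 21887 protein-coding genes, 7679 (35.1%) had at least 1 region in the gene or within 5 kb.

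Tead1, which encodes a DNA-binding partner of the Hippo pathway coactivators YAP and TAZ, had mostly negative regions. Most regions of the whole list were negative too (67.4%), and the split of signs at Tead1 was not compared with other genes. The gene spans positions 112679356 to 112906784 of chromosome 7 (mm10), and 7 regions lay in it or within 5 kb, 6 negative and 1 positive. The strongest, of 212 bp at 112759413 to 112759624 inside the gene, scored -212. The other negative regions inside the gene scored -81.0, -64.6, -87.7 and -85.3, the positive one scored 53.2, and the last, 1.10 kb beyond the upper end of the gene, scored -30.1. Tead1 is a long gene. Among the 200 protein-coding genes closest to it in length the median was 4 regions (quartiles 1 and 6), and Tead1 stood at percentile 78.3.

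The genes of the sorted antigens and the glucocorticoid receptor each had at most 2 regions within 5 kb. Pdgfra (chromosome 5, 75151322 to 75198206) had 1 positive region inside the gene with a score of 109 and 1 negative region with a score of -137. Tnfrsf9, which encodes CD137, had no region in the gene or within 5 kb, and the nearest within 50 kb was a negative region of 389 bp 17.7 kb from the gene (score -225). Nr3c1, the glucocorticoid receptor gene, had a negative region of 361 bp 1.96 kb from its upper end (score -120.1) and a positive region inside the gene (score 39.3). Within 50 kb it had 5 regions, 4 negative, the strongest of them 370 bp wide (score -256) and outside the 5 kb window.

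**Figure D2:**
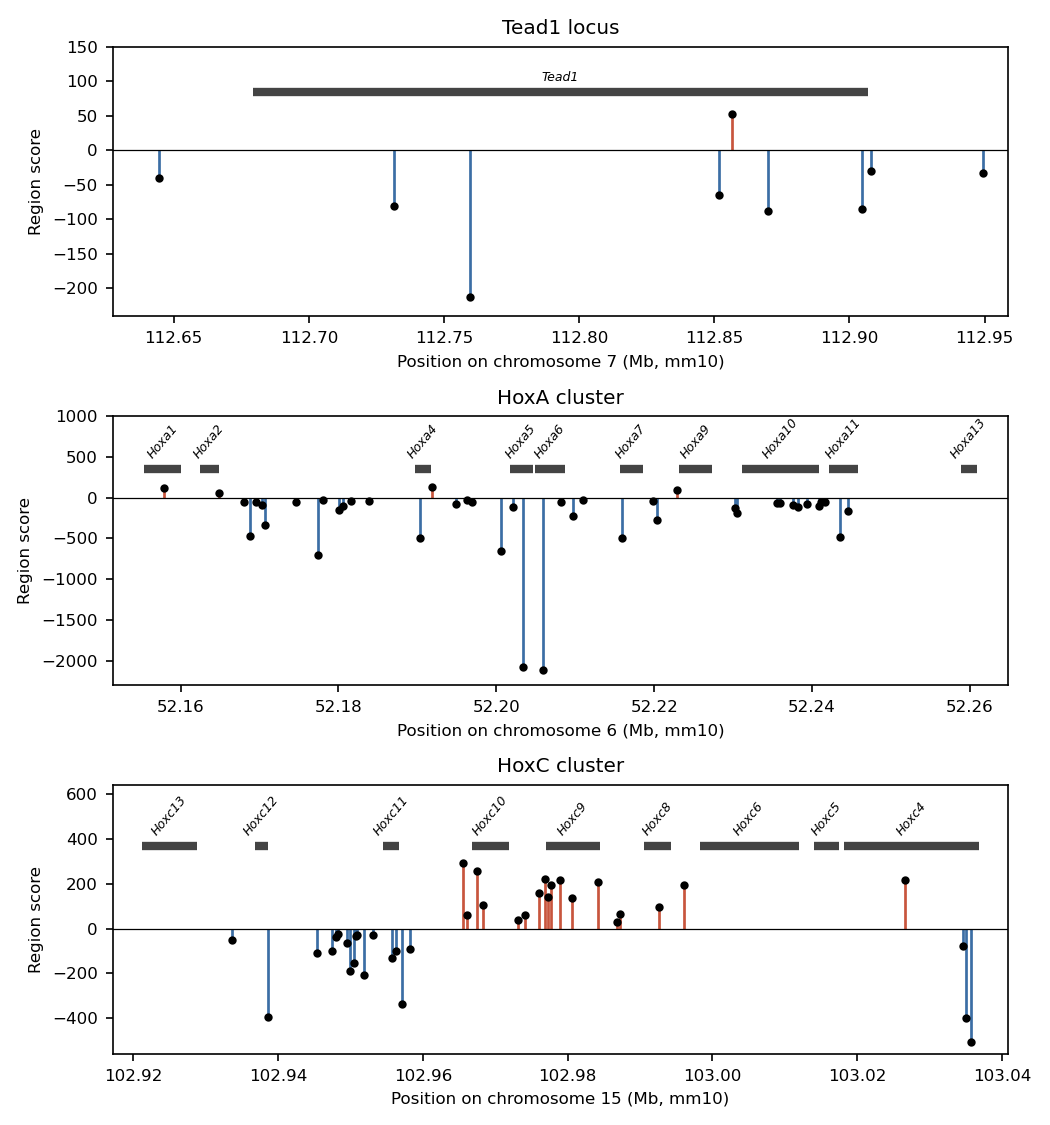
Region scores (vertical axis, the authors' score, no unit) by position in Mb (horizontal axis) at Tead1, HoxA and HoxC; each point with its line is 1 region, blue for negative and red for positive, and grey bars are genes (Hoxa3, whose model spans several neighbours, is not drawn). HoxA is negative in 38 of 42 regions, whereas the 38 HoxC regions fall into 3 runs of 1 sign each.

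Genes of the Hippo pathway and the TEAD family carried regions in 23 of 33 members, against 17.3 expected and a central 95% range of 13 to 22 over random lists. This count did not stand above chance with any of 3 other settings (gene ends only, 50 kb on both sides, or only regions with an absolute score of 100 or more). Of its 60 regions 65.0% were negative (52.4 to 75.8), close to the genome-wide share. Members with only negative regions numbered 7 and with only positive regions 6. Taok1, a kinase upstream of the pathway, had a single region of score -203. The YAP target genes went both ways. Ccn1 and Ccn2 each had 1 positive region, with scores of 173 and 40.1, whereas Ankrd1 had 2 negative regions, the stronger with a score of -139, and Axl had 1 of each sign, the stronger with a score of -78.2. Amotl1 had 6 of 7 regions negative (strongest -73.1) and Fat4 3 of 5 (strongest -51.9), although their gene-end regions were positive (32.6 and 47.7).

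Glucocorticoid response genes had regions in 21 of 30 members against 11.7 expected (range 8 to 16). Their 68 regions were negative in 76.5% (65.14 to 84.97), and 11 members had only negative regions against 2 with only positive regions. This share of negative regions stood at percentile 80.9 of the random lists, inside their central 95%. Fkbp5, which encodes a chaperone that restrains the receptor, had 6 regions, all negative. Errfi1 had 5 and Hsd11b1, which encodes the enzyme that regenerates active glucocorticoid, had 4, again all negative. Dusp1, a phosphatase gene induced by glucocorticoids, had a region of score -84.1 at its gene end. Other members had positive regions, with strongest scores of 145 at Sgk1 (2 of 3 positive), 127 at Nfkbia (1 region) and 113 at Fbxo32 (1 of 2 positive). Per1, Mt1, Mt2, Angptl4 and 5 other members had no region. Both libraries were treated with dexamethasone, so the regions of this list cannot be read as a response to it.

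Transcriptional and signalling regulators of adipogenesis had regions in 18 of 26 members (10.5 expected, range 6 to 15), and their regions ran against the genome-wide sign. Of 104 regions only 20, or 19.2% (12.8 to 27.8), were negative, which was percentile 0.01 of the random lists. By member the split was closer, with 6 members that had only positive and 5 that had only negative regions. Ebf1, an early B-cell factor active in adipocyte differentiation, had 24 positive regions and 1 negative. Its relative Ebf2, a beige and brown precursor regulator, had 19 and 3, with a score of 642 at its gene end. Pparg, the master regulator of fat cell formation, had 6 regions, all positive, the strongest with a score of 102. Gata2, whose product holds back adipogenesis, had 6, all positive, the strongest with a score of 710.5. Without Ebf1 and Ebf2 the negative share was 28.1% (18.1 to 40.8) of 57 regions, at percentile 0.57. Cebpa, Cebpb and Cebpd had none. At gene ends alone, the list's count was at percentile 56.7 of the random lists and no longer stood above chance. The negative share was then at percentile 18.1 (1 of 4 regions), and at 6.40 for regions of absolute score 100 or more (7 of 34), both inside the central 95%.

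Wnt signalling genes showed the same tilt, with 19 of 25 members carrying regions (11.1 expected, range 7 to 15) and 34.8% of 66 regions negative (24.5 to 46.9; percentile 0.59). Positive regions lay at the receptor gene Fzd1 (score 457), at Fzd4 with 5 regions, all positive, and at Tcf7l2, which had 12 of 14 positive. Axin2, a feedback target of the pathway, went the other way with 6 regions, all negative, the strongest with a score of -328. This count, too, did not stand above chance at gene ends alone (percentile 56.8). The negative share was inside the central 95% there (percentile 7.91, 2 regions) and for regions of absolute score 100 or more (7.06, 15 regions).

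Adipose progenitor markers had regions in 12 of 22 members (7.29 expected, range 3 to 11), and 8 of the 12 had only positive regions. Of their 22 regions 36.4% were negative (19.7 to 57.0), at percentile 3.90 of the random lists and inside their central 95%. This share was also inside at gene ends (percentile 17.0), with 50 kb on both sides (8.455), for strong regions (19.2) and against the reduced background (3.76). Without Col15a1 it was at 0.78, but that gene held 5 of the 8 negative regions, so leaving it out had to lower the share. Col15a1 had a region of score 242 at a gene end and 5 negative ones, and Wnt2, Cd24a and Itgb1 scored 69.1, 29.7 and -36.0. This list did not stand above chance under any of the 4 other settings tried for lists, where its percentiles were between 55.3 and 97.43.

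Genes of the mature adipocyte had regions in 15 of 27 members (8.86 expected, range 5 to 13), but few of these were strong. Fabp4, Aqp7, Plin1 and Pck1 had gene-end regions with scores of 55.6, 51.8, 51.4 and -41.2. The strongest region at Aqp7 lay outside its gene ends and scored -62.5. Only 2 members had a region of absolute score 100 or more against 2.63 expected (range 0 to 6), and with 50 kb on both sides the list was at percentile 95.6, under the threshold.

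The brown and beige fat genes had regions in 12 of 22 members, inside the random range of 6 to 13, although 9 had a region of absolute score 100 or more against 3.15 expected (range 0 to 6). They included the protein-coding gene with the most regions, Prdm16, a determinant of brown and beige fat identity, with 51 regions, 46 of them negative. Tbx1, a beige marker, held the most negative score of all, -2569 over 1399 bp (chromosome 16, 18581704 to 18583102, inside the gene). Cox8b had 1 region, with a score of -186. Ucp1 had none. Of this list's 120 regions 71.7% were negative; without Prdm16 58.0% were, and without Prdm16 and Ebf2 78.7%. The other genes with most regions were Zfhx3 (36, of which 21 positive), Tshz2 (35, of which 33 negative), Wwox (35) and Cdh13 (34). Unlike the count at Tead1, the counts at Prdm16 and these genes were not set against genes of like length.

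Genes that mark fat depots and body position had regions in a larger share of members than any other of the 18 lists. Of 28 depot identity genes 26 had a region (8.42 expected, range 4 to 13), and 18 had a region of absolute score 100 or more against 2.59 expected (range 0 to 6). The 145 regions were 70.3% negative (62.5 to 77.2), so the list held both signs, but most members held mainly 1. Shox2 (strongest score -932), Tbx5 (19 regions, all negative), Nr2f1, Irx2, Irx3 and Irx5 had only negative regions, and En1 and Tbx15 had 7 of 8 and 8 of 10 negative. Osr1, a marker of embryonic mesenchyme, had 6 regions, all positive, with a score of 1484 at its end (chromosome 12, 9580358 to 9581531). Meox2 had 7 and Hoxc10 8, all positive.

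The HOX genes, which encode position along the body axis, had regions in 31 of 39 members (7.56 expected, range 3 to 12). Number and sign differed between the 4 clusters. HoxA held 42 regions, 38 negative, with scores of -2115 (2319 bp at chromosome 6, 52204715 to 52207033) and -2076 (1909 bp) at Hoxa5 and Hoxa6. Hoxa4 and Hoxa7 had regions of -497 and -492. HoxB held 38 regions, 35 negative. HoxC held 38 regions in 3 runs. The 17 regions of the first 24.9 kb, around Hoxc11 and Hoxc12, were negative, the next 18 over 61.4 kb, around Hoxc10, Hoxc9 and Hoxc8, were positive, and the last 3, at Hoxc4, were negative; 1 of the 18 positive regions also lay in Hoxc4. HoxD held 4.

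**Figure D3:**
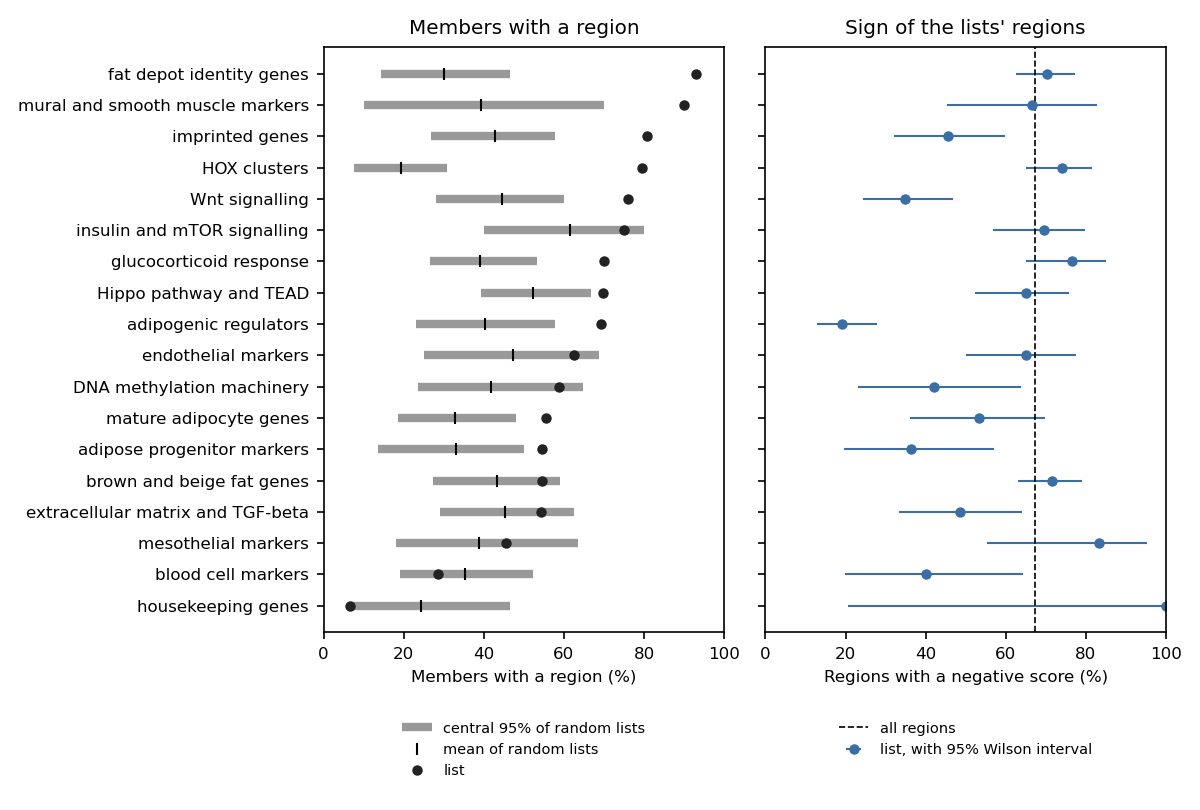
Left, percent of members with a region in the gene or within 5 kb (points) for each of the 18 lists fixed before the data were examined, with the mean (tick) and central 95% (bar) of 10000 matched random lists; right, percent of the lists' regions with a negative score, with 95% Wilson intervals and the genome-wide share (dashed). Depot identity genes reach 26 of 28 members, and adipogenic regulators have 19.2% negative regions.

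At single genes outside the lists, large positive scores were found at the mesenchymal regulators Ebf3 (4147 over 3191 bp, chromosome 7, 137308629 to 137311819, inside the gene), Prrx1 (1391) and Foxl1 (1217). The region at Mab21l1 (2903) also lies within Nbea, and a region of score 716 inside Nfix is 0.303 kb from Lyl1, so neither can be assigned to a single gene. Grik5 (711) and Irs3 (412) complete the positive gene-end set. The negative set held Scx, a tendon transcription factor gene (-582), and a region of score -2088 shared by Tmem267 and 4833420G17Rik on chromosome 13.

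Markers of other cell types the sort could have carried along differed in how often they had regions. Blood cell markers had regions in 6 of 21 members (7.44 expected, range 4 to 11), with Runx1 the strongest (286) and Csf1r, Laptm5 and Vav1 at -63.7, 53.5 and -46.4. Mesothelial markers had regions in 5 of 11 (4.27 expected), with 8 of their 12 regions at Wt1. Lrrn4, Bnc1 and Upk1b had 1 negative region each. Endothelial markers had regions in 10 of 16 (7.57 expected, range 4 to 11), and in 7 at an absolute score of 100 or more (2.65 expected, range 0 to 6), among them Tek (163), Eng (-115), Kdr and Erg. Mural and smooth muscle markers had regions in 9 of 10 (3.92 expected, range 1 to 7), among them Notch3 (-291), Des (-70.7), Abcc9 and Kcnj8. With 50 kb on both sides or only regions of absolute score 100 or more, this list's percentiles were 97.495 and 94.6, under the threshold.

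Imprinted genes, whose methylation depends on parental origin, had regions in 21 of 26 members (11.1 expected, range 7 to 15). Peg10 and Sgce shared a region of score -238, and Peg3 and Gnasas1 had gene-end regions of 117 and 149.8. The strongest region at Gnasas1, shared with Gnas, scored 404, the largest absolute score in this list. DNA methylation machinery genes had regions in 10 of 17 members (7.10 expected, range 4 to 11), with Mbd3 at -202, Mbd2 at 130.0, Mbd1 at -113 and Dnmt3l at 31.1. Extracellular matrix and TGF-beta genes had regions in 13 of 24 (10.9 expected), with Tgfb2 at -167, Tgfbr2 at 115, Mmp14 at -61.8 and Acta2 at -94.9, or -19.2 at its gene end. Insulin and mTOR genes had regions in 15 of 20 (12.3 expected), with Irs1 at 335, Pik3r1 at -308 and Rictor at -129.6. Housekeeping genes had a region in 1 of 15 members (3.65 expected). In all, 10 of the 18 lists stood above chance and 0 below it.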

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

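The alternatives on score, width, local shifts, background, left-out members and the signs at gene ends were chosen after seeing the data, and the other ones before. With 1 library per group leaving out a library was impossible. No paired analysis was possible because no replicates exist. Not run were a minimum methylation difference of 0.3, a minimum of 10 CpG sites, matching on CpG sites and all motif settings, since the list gives neither levels nor CpG numbers and no genome sequence was used. The unknown depth limits every value, because the list does not tell an unchanged stretch from one with few reads. Negative regions stayed in the majority under each of the 5 alternatives tried for their share. The cause of the changes given here was not tested, except that stricter minimums leave fewer regions by construction.

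The negative share was 69.5% of covered base pairs and 69.1% of regions at least 100 bp wide. An absolute score of at least 100 left 5281 regions, and a width of at least 100 bp left 19695. The median absolute score was 67.1 when weighted by length and 67.5 at a width of at least 100 bp. The fold of gene-end regions over random placement was 1.17 with a gene-end window from 5000 bp outside to 1000 bp inside, 1.10 with protein-coding genes only, 1.68 for an absolute score of at least 100, and 1.10 when regions were moved by up to 500 kb. For gene bodies it was 1.24 with a window from 1000 bp outside to 100 bp inside, 1.21 with the wider window, 1.26 with protein-coding genes only, 1.24 for strong regions and 1.06 when regions were moved.

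At gene ends alone, 4 lists no longer stood above chance, with percentiles of 56.65 (adipogenic regulators), 56.755 (Wnt), 60.9 (Hippo and TEAD) and 96.0 (progenitor markers), while DNA methylation machinery (98.2) and endothelial markers (99.96) now did. With 50 kb on both sides, mature adipocyte genes (95.6), Hippo and TEAD (64.9), progenitor markers (95.1) and mural markers (97.495) no longer did, and brown and beige genes (99.7) now did. For strong regions, Hippo and TEAD (69.4), progenitor markers (55.3) and mural markers (94.6) no longer did, mature adipocyte genes lay on the other side of the median (36.4), and brown and beige genes (99.9) and endothelial markers (99.7) now did. Without receptor, Zfp and unnamed genes in the background, progenitor markers were at 97.43. The glucocorticoid, depot identity, HOX and imprinted lists stood above chance under all 4 of these settings.

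The negative share left its interval for adipogenic regulators without Ebf1 and Ebf2 (28.1%), brown and beige genes without Prdm16 (58.0%), progenitor markers without Col15a1 (18.8%) and also without Wnt2 (15.4%), insulin and mTOR genes without Pik3r1 and Rptor (56.8%), and mesothelial markers without Wt1 (100%) and also without Bnc1 (100%). In the other 27 cases it stayed inside. Against random lists, the low negative share left the outer 5% for adipogenic regulators at gene ends (percentile 18.1) and for strong regions (6.40), and for Wnt genes likewise (7.91 and 7.06). It entered it for extracellular matrix genes (1.895) and housekeeping genes (2.29) with 50 kb on both sides, and for imprinted genes against the reduced background (2.38).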

Other observations

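The gene families given here, the list of neural developmental regulators, the explanation by depot of origin, and the tests on the neural list and on a library-wide difference were chosen after results were seen. In all, 20 families were examined. All 25 regions at Iroquois homeobox genes, which pattern limbs and body axis, were negative, and 5 of the 6 genes had one (1.10 expected over random lists, range 0 to 3). That share was at percentile 74.4 of the random lists, inside their central 95%. Irx2, Irx3 and Irx5, with 5, 7 and 10 of these regions, also belong to the depot identity list, so they are counted again here. LIM homeobox genes had regions in 8 of 12 members (4.33 expected, range 2 to 7), and 37 of 38 regions were negative (percentile 91.1, also inside), 14 each of them at Lmx1a and Lmx1b. The early B-cell factor family went the other way, with 9 of 68 regions negative (13.2%, 7.12 to 23.3). That was percentile 0.52, but 14.5 for strong regions. Ebf1 and Ebf2, with 25 and 22 of these regions, were already counted among the adipogenic regulators. Forkhead genes had regions in 20 of 44 members (12.9 expected, range 8 to 18) and keratins in 18 of 50 (10.5 expected, range 5 to 16). The counts of LIM homeobox, forkhead and keratin genes did not stand above chance at gene ends (percentiles 59.2, 87.6 and 90.2), nor those of LIM homeobox and keratin genes for strong regions (93.5 and 60.6), nor those of forkhead and Iroquois genes with 50 kb on both sides (95.3 and 83.2). Olfactory receptors had regions in 17 of 1117 members against 72.8 expected (range 57 to 89). Vomeronasal receptors had them in 4 of 357 against 56.8, and Zfp zinc finger genes in 81 of 372 against 124. Random lists were matched on neither CpG content nor read coverage, so these low counts cannot be read as unchanged methylation. Of 58 clustered protocadherins 36 had a region, but they shared 3 distinct regions.

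Neighbouring regions tended to share their sign. Of 1896 neighbours less than 0.5 kb apart 98.0% had the same sign, against 56.0% when signs were shuffled. The share was 64.6% between 1 and 5 kb, and 59.1% between 100 and 1000 kb. The shuffle treats every region as separate. The list does not tell whether the closest neighbours are parts of 1 longer stretch, which would share a sign. The 1 Mb windows with most regions held Prdm16 (70 regions, chromosome 4), the HoxA cluster (64, chromosome 6) and the HoxB cluster (60, chromosome 11).

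Strong regions, of absolute score 100 or more, were found at 18 of 28 depot identity genes. Neighbouring genes that share regions are not the whole cause, since with 1 member kept per run of genes closer than 100 kb the list had 15 of 25 members and stood at percentile 100. That large scores arise at developmental regulators whatever the tissue stays open, since 60 neural regulators, listed after the regions at their members Lmx1a and Lmx1b had been seen, stood at percentile 39.04, but 5 of 10 other regulator families stood above chance without their depot-list members, among them forkhead (12 of 44 members, 4.09 expected) and nuclear receptor genes (16 of 41, 7.40 expected). These families were chosen after the strongest regions, some of them at EBF and T-box genes, had been seen, and CpG density was not measured. That the libraries came from different fat depots is a candidate explanation that was not tested, because the labels do not give the depot and the full list's percentile of 100 is the pattern itself.

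Chromosome X held 4.21 times fewer regions per Mb than the autosomes. Gene content does not account for it, since within windows of protein-coding genes the autosomes still had 3.43 times as many regions per Mb. Lower read depth on X, as in male DNA, might leave fewer regions and lower scores there, and X lay below every autosome in median absolute score (36.5 against 46.9 to 53.3) and median width (93 against 105 to 119 bp). Per bp the median was 0.396 against a lowest autosome of 0.407, with an interval (0.381 to 0.410) that includes it, and smaller real differences on X would give low values too, so depth stays open. The sex of the animals is not given in the sources used here. Chromosome Y held 15 regions, which cannot settle the sex because the list holds no read counts. No biological explanation was tested.

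Negative regions made up 67.4% of the list. A few dense domains do not account for this, because without the 128 of 2507 windows of 1 Mb with most regions the share was 67.5%. A library-wide difference in depth, conversion or methylation level could give such an excess on every chromosome, and the largest distance of an autosome from the pooled share was 2.28 percentage points. A genome-wide difference between the sorted populations would look the same, so these cannot be told apart with 1 library per group and no levels.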
